A study of Mus musculus with 7 samples.

How the data were processed

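RNA from bone marrow HSCs of C57BL/6 mice, sorted as Hdc-GFPhi (3 samples) or Hdc-GFPlo (4 samples), was measured by RNA sequencing. Per the labels' protocols, RNA was isolated from 500 sorted cells with a PicoPure kit, cDNA was amplified with the SMARTer Ultra Low Input kit, which does not mark strand, and libraries were built with Nextera XT. Molecular identifiers are not mentioned in the labels, so duplicate reads from amplification cannot be removed from the counts. Per the submitters' processing notes, reads were processed with bcl2fastq 1.8.4, TopHat2 (written as 2.0.4 or 2.04), Bowtie2 and HTSeq 0.6.1, with the mouse build mm9. The gene annotation, the strand setting and any read filters are not given in the sources used here. The deposited values are raw read counts per gene, not normalized, with 1 column per library and no pooling, and genes are given by symbol without coordinates. A reference of the build mm9 was not used here, so no coordinates are printed. Reads of overlapping or antisense genes and of near-identical copies cannot be separated in such counts.

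Each column was matched to its sample by the library code that stands in that sample's description. The columns name the fractions GFP plus and GFP minus where the sample labels write GFPhi and GFPlo. Groups and replicate numbers came from the sample titles. The sorted fraction of Hdc-GFPlo replicate 4 is labelled GFP negative, unlike that of the other Hdc-GFPlo samples, and it was kept in its group and left out in turn. All 7 columns were used. Total counts were 22021928, 23688672 and 21090553 for Hdc-GFPhi replicates 1 to 3 and 20572248, 19606124, 22472061 and 20756629 for Hdc-GFPlo replicates 1 to 4. At these depths 3 counts, the upper limit that a count of 0 allows, equal 0.127 to 0.153 CPM. The common biological coefficient of variation was 35.3%.

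In R 4.3.3 with edgeR 4.0.16, genes were filtered with filterByExpr (minimum count 10), which left 12917 of 23284 genes, and 6927 genes had no count in any library. Libraries were scaled by TMM factors, and Hdc-GFPhi was compared with Hdc-GFPlo by edgeR's quasi-likelihood F test with robust settings and group as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. Levels are TMM-normalized CPM, as mean ± SD over 3 and 4 libraries. Log2 CPM for correlations and list deviations used a pseudocount of 2. The 20 gene lists and the rules for named genes, tests and alternatives were fixed before the data were examined. Lists were tested with limma 3.58.1 on voom values, by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, with Benjamini-Hochberg adjustment over the 20 lists. Exact permutation tests used all 35 splits of the 7 libraries and were two-sided.

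The named genes were Hdc, then 13 genes fixed in advance (Slamf1, Itga2b, Procr, Kit, Ly6a, Cd34, Cd48, Vwf, Hrh2, Flt3, Mpo, Mki67 and Cdk6). To these were added the 10 largest folds in each direction among genes that passed and whose groups did not overlap at a mean of at least 5 CPM or, as fewer than 5 passed, the 5 smallest unadjusted p in each direction under the same conditions. The 3 members of each list with the smallest unadjusted p completed the rule, and a few genes that it takes are not reported here. Other genes named (Ccnb1, Elane, Fos, Gapdh, Ngp, S100a8 and those named in the closing section for single libraries) were chosen after their values were seen.

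The steps were tested on simulated data first. In 5 simulations of the comparison of Hdc-GFPhi with Hdc-GFPlo over 12917 genes, with 200 genes changed each time, the edgeR step recovered 11.3% of genes changed 1.5-fold, 51.3% of those changed 2-fold and 75.2% of those changed 4-fold, with 35 false calls in all. A shift of the mitosis list by 0.5 on the log2 scale was called in 5 of 5 simulations, and the other lists in 0 of 95 tests. Genes were drawn independently of each other there, unlike the real list members (estimated correlation 0.567 for mitosis). The 0 of 95 therefore does not give the rate of false list calls in these data. The recovery rates and false calls of genes also hold only for genes that vary independently. With the real counts, a split of the libraries other than the real one passed as many as 10 lists.

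Alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), no filter or a stricter one (at least 5 CPM in 3 libraries), DESeq2 1.42.0, limma voom with quality weights, no robust setting, thinning to equal depth, a replicate block (without Hdc-GFPlo replicate 4, which has no partner) and leaving out each library. Added after the data were seen were a fit with the trend on GC content and transcript length removed, a fit without Hdc-GFPhi replicate 1 and Hdc-GFPlo replicate 4, and DESeq2 without Hdc-GFPlo replicate 4. GC content and length came from the reference annotation of another build, where 20882 of 23284 genes matched by symbol and 1941 by a synonym.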

Results

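The series profiled hematopoietic stem cells (HSCs) from the bone marrow of C57BL/6 mice carrying a green fluorescent protein (GFP) reporter of Hdc, the gene for histidine decarboxylase, the enzyme that makes histamine. HSCs were sorted into a bright fraction, Hdc-GFPhi (3 libraries), and a dim fraction, Hdc-GFPlo (4 libraries), with 500 cells per library, and the design asked which genes differed in expression between these fractions. Counts were given for 23284 genes by symbol, without coordinates. Total counts ranged from 21090553 to 23688672 in Hdc-GFPhi and from 19606124 to 22472061 in Hdc-GFPlo, and 13483 to 14185 genes had at least 1 count in a library. The 10 most counted genes took 2.63% to 3.01% of a library. Pairs of libraries correlated at 0.892 to 0.951 (Pearson's r of log2 CPM, counts scaled to library size, across genes, which are not independent replicates), and Hdc-GFPlo replicate 2 had the lowest values. Pairs of libraries differed by more than counting noise, with chi-square per degree of freedom between 24.98 and 137. Separate amplification gives such an excess too, so it does not show that the samples were independent, and each library was kept as the replicate its label names. Nothing in the labels says that the replicates were separate animals, so p-values measure the spread between these samples, which may be technical. Detection floors cover counting error only, although amplified reads are not independent molecules. The SDs and SEs given below reflect the spread between libraries.

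Hdc itself, which drives the reporter used for the sort, was measured at 30.1 ± 10.002 CPM in Hdc-GFPhi (SD, n = 3) and 14.7 ± 7.27 CPM in Hdc-GFPlo (SD, n = 4), a ratio of 2.039. Counts were 850, 450 and 714 in the Hdc-GFPhi libraries and 334, 314, 483 and 92 in Hdc-GFPlo replicates 1 to 4. The groups overlapped, because Hdc-GFPhi replicate 2 (18.7 CPM) lay below Hdc-GFPlo replicate 3 (21.6 CPM). The lowest level, 4.44 CPM, was in Hdc-GFPlo replicate 4, the only sample of its group whose sorted fraction was labelled GFP negative. The difference did not pass the test over all genes (log2 fold change 1.03, SE 0.45, edgeR adjusted p = 0.397, unadjusted p = 0.0448). An exact two-sided permutation test of log2 CPM gave p = 0.143, where the smallest p that 35 splits allow is 0.0286. The log2 fold change was 0.52 without Hdc-GFPhi replicate 1 and Hdc-GFPlo replicate 4.

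Among genes with a mean of at least 5 CPM whose groups did not overlap, the 5 with the smallest unadjusted edgeR p in each direction were as follows. Pf4, the platelet chemokine, was measured at 186 ± 48.1 CPM in Hdc-GFPhi against 87.0 ± 13.7 CPM in Hdc-GFPlo (log2 fold change 1.09, SE 0.18), and Cxcr2, the chemokine receptor of neutrophils, at 18.0 ± 7.20 against 4.11 ± 1.65 CPM (2.13, SE 0.41). Mfsd2b, an exporter of sphingosine 1-phosphate (0.55, SE 0.09), Slc1a5, a glutamine transporter (0.65, SE 0.12), and Gpr97, an adhesion receptor of granulocytes (0.82, SE 0.14), were the other leading genes with higher values. Lower values in Hdc-GFPhi were led by Eltd1, an adhesion receptor known from endothelium, at 580 ± 1.32 against 815 ± 32.2 CPM (log2 fold change -0.49, SE 0.06), and by Dpp4, the surface peptidase CD26, at 64.3 ± 4.71 against 107 ± 8.60 CPM (-0.73, SE 0.11). Phf6, a nuclear zinc finger protein (-0.73, SE 0.11), Abi2, an Abl kinase interactor (-0.83, SE 0.13), and Rbm44, an RNA-binding protein (-2.58, SE 0.37; 23 to 39 counts per library against 132 to 184), followed. All 10 had Hdc-GFPhi libraries entirely on one side of the Hdc-GFPlo libraries, which was a condition of their selection, and none of them passed the edgeR test over all genes.

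Of 12917 genes tested, 0 passed edgeR's quasi-likelihood test at an adjusted p of 0.05, and the smallest adjusted p was 0.211. At an unadjusted p under 0.05 there were 1579 genes, 635 higher and 944 lower in Hdc-GFPhi, where 646 are expected with no effect. That count was 997 without Hdc-GFPhi replicate 1, and with library totals as the only scaling the split was 826 higher and 768 lower. DESeq2 called 355 genes, 73 higher and 282 lower, the 10 genes above among them, and limma with quality weights called 0. The Hdc-GFPhi libraries lay entirely above or entirely below the Hdc-GFPlo libraries for 11.9% of the tested genes (6.02% above, 5.87% below). Chance gives 5.71% on average over splits of the libraries. Single splits can depart from that average because genes vary together, and their shares were not computed, so the excess was not tested.

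**Figure D1:**
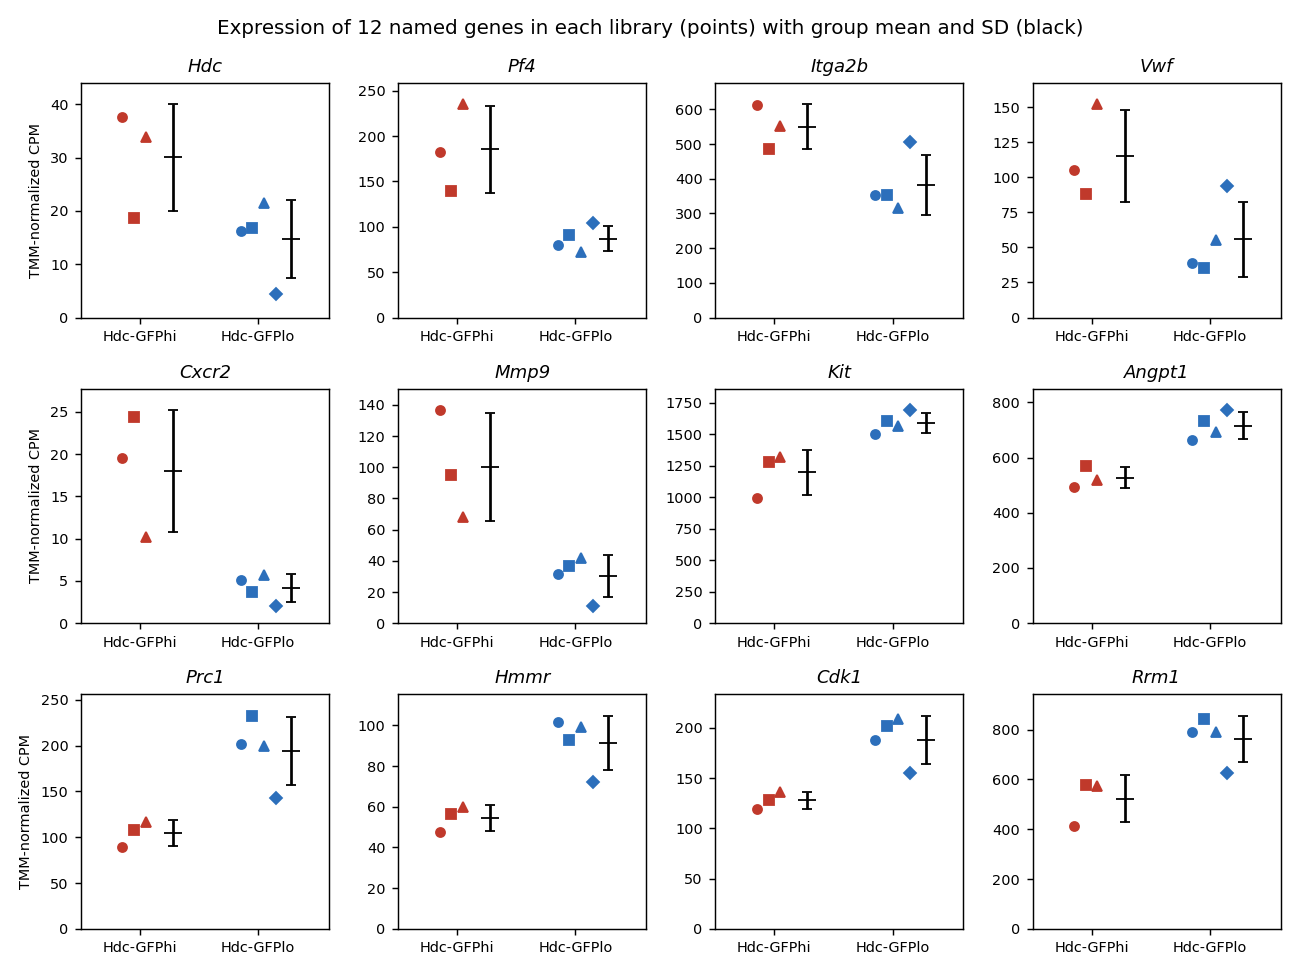
TMM-normalized CPM of 12 genes in each library. Points are libraries (circle, square, triangle and diamond for replicates 1 to 4), with black bars for the group mean and SD (n = 3 Hdc-GFPhi, n = 4 Hdc-GFPlo) and a vertical axis from 0 in each panel. Pf4, Cxcr2 and Mmp9 lay higher and Kit, Angpt1, Prc1, Hmmr, Cdk1 and Rrm1 lower in all 3 Hdc-GFPhi libraries than in any Hdc-GFPlo library, and Hdc, Itga2b and Vwf overlapped.

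Genes of mitosis were lower in Hdc-GFPhi as a group. All 32 measured members of the mitosis list had lower values (median log2 fold change -0.56), and 23 of them fell when adjusted over the list alone. Among these were Prc1, a protein of the central spindle (104.7 ± 14.1 against 194.5 ± 37.3 CPM, log2 fold change -0.89, SE 0.16), the spindle protein Hmmr (-0.75, SE 0.15), the mitotic kinase Cdk1 (-0.56, SE 0.12) and the cyclin gene Ccnb1 (-0.89, SE 0.19). The proliferation marker Mki67 did not pass (-0.29, SE 0.20). The summed CPM of the list was 2965, 3345 and 3386 in the Hdc-GFPhi libraries and 4952, 5161, 5103 and 3492 in Hdc-GFPlo replicates 1 to 4, so replicate 4 of Hdc-GFPlo, which also had the lowest Hdc level, lay close to the Hdc-GFPhi libraries. The list passed limma's camera test (adjusted p = 6.32e-20 over 20 lists), and its adjusted p was 0.470 with an estimated correlation between genes. The mean deviation of the members was lower in every Hdc-GFPhi library than in any Hdc-GFPlo library (exact two-sided permutation p = 0.0571, Benjamini-Hochberg 0.229 over 20 lists). DESeq2 called 15 members, all lower, and edgeR called 0 over all genes.

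DNA replication genes shifted in the same direction by less. Of 33 members 28 had lower values (median log2 fold change -0.17), and 0 passed when adjusted over the list alone by edgeR, with 7 at an unadjusted p under 0.05 and 2 called by DESeq2. Those 2 were Rrm1 and Rrm2, the subunits of ribonucleotide reductase, at 523 ± 93.5 against 763 ± 93.8 CPM and 142 ± 9.09 against 189.7 ± 22.7 CPM, and Ccne2, the gene for cyclin E2, had a log2 fold change of -0.70 (SE 0.22). The camera adjusted p was 4.63e-05, or 0.584 with an estimated correlation. Without Hdc-GFPhi replicate 1 the median was -0.09 and the adjusted p 0.0527, and without Hdc-GFPlo replicate 4 the median was -0.26. Without both libraries the median was -0.16 and the list passed camera (adjusted p = 9.33e-06). The mean deviations of the libraries overlapped between the groups (exact two-sided permutation p = 0.143).

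Megakaryocyte and platelet genes, part of which HSCs also express, were higher in Hdc-GFPhi as a group. Values were higher for 22 of 26 members (median log2 fold change 0.27), and Pf4 rose when adjusted over the list alone. Vwf, the gene for von Willebrand factor, was at 115 ± 33.1 CPM against 55.7 ± 26.9 CPM (log2 fold change 1.05, SE 0.33), and Itga2b, the gene for the surface integrin CD41, at 550.3 ± 64.8 against 382 ± 85.6 CPM (0.53, SE 0.16). DESeq2 called Pf4, Vwf and Itga2b, while edgeR called none of them over all genes (adjusted p = 0.211, 0.293 and 0.283). For Vwf and Itga2b, Hdc-GFPlo replicate 4 lay among the Hdc-GFPhi libraries. It had 93.9 CPM of Vwf and 507 CPM of Itga2b against 34.99 to 55.1 and 314 to 354 CPM in the other 3 libraries of its group. For Pf4 it lay below every Hdc-GFPhi library, at 104 CPM against 139 to 235 CPM. The list passed the camera test (adjusted p = 1.68e-04, or 0.584 with an estimated correlation), and its median was 0.44 without Hdc-GFPhi replicate 2. Its mean deviations overlapped between the groups (exact two-sided permutation p = 0.0857).

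Genes of long-term HSC identity did not move together. Of 35 members 17 had higher and 18 lower values (median log2 fold change -0.01, mean 0.00, camera adjusted p = 0.612), and Angpt1, Eya1 and Kit fell when adjusted over the list alone. Angpt1, the gene for angiopoietin 1, was at 527 ± 38.8 against 716 ± 47.9 CPM, Eya1, a transcriptional coactivator, at 36.6 ± 3.91 against 54.6 ± 4.80 CPM, and Kit, the receptor for stem cell factor, at 1198 ± 179.5 against 1590.3 ± 81.3 CPM. Limma's fry test for change in either direction gave an adjusted p of 0.00490 for this list, and its test for change in a common direction 0.596. Fry does not compare a list with genes outside it. At an unadjusted edgeR p under 0.05, 1 of the 35 members was higher and 5 were lower. Over all 12917 genes tested these counts were 635 and 944, so a change particular to this list was not shown. Surface markers used to define HSCs and progenitors had small differences that did not pass edgeR, with log2 fold changes of -0.11 (SE 0.18) for Slamf1, -0.01 (SE 0.12) for Procr, -0.06 (SE 0.19) for Ly6a, -0.26 (SE 0.12) for Cd34, -0.18 (SE 0.29) for Cd48 and -0.14 (SE 0.16) for Flt3. The signs for Slamf1, Procr and Ly6a turned when a library was left out.

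Regulators of quiescence and the histamine pathway did not shift as lists. Of 32 cell cycle inhibitors and quiescence genes 21 had higher values (median log2 fold change 0.08, camera adjusted p = 0.958), with Cdk6 at 0.08 (SE 0.10). Bmi1, a Polycomb protein (-0.64, SE 0.17), and Rbl1, a relative of the retinoblastoma protein (-0.79, SE 0.22), had lower values, and DESeq2 called both. In the histamine list 6 of 8 members were lower (median -0.25, -0.32 to -0.08 over the fits without a library, camera adjusted p = 0.392), and Slc18a2, whose product loads histamine and other monoamines into vesicles, fell when adjusted over the list alone (262 ± 22.9 against 332 ± 22.4 CPM, log2 fold change -0.34, SE 0.09). Maoa had a log2 fold change of -0.55 (SE 0.22), and Maob was counted 0, 0 and 3 times in Hdc-GFPhi and 24, 118, 16 and 0 times in Hdc-GFPlo. The histamine receptor gene Hrh2 had 79 to 183 counts in 6 libraries and 1 count in Hdc-GFPlo replicate 4 (log2 fold change 0.48, SE 0.92).

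Neutrophil and monocyte genes were higher in Hdc-GFPhi. Values were higher for 22 of 24 members (median log2 fold change 0.78), and Cxcr2 and the gelatinase gene Mmp9 rose when adjusted over the list alone (Mmp9 100.03 ± 34.6 against 30.4 ± 13.6 CPM, 1.72, SE 0.40). Fpr2, a formyl peptide receptor gene, had a log2 fold change of 1.59 (SE 0.59). The summed CPM of the list was 8408 to 11541 in Hdc-GFPhi and 4528 to 9714 in Hdc-GFPlo. The most abundant were granule and calcium-binding protein genes such as Ngp (1820 ± 323.7 against 1342 ± 634 CPM) and S100a8 (1443 ± 335 against 845 ± 352 CPM). The camera adjusted p was 9.59e-10, or 0.470 with an estimated correlation. The mean deviation of the list was higher in every Hdc-GFPhi library than in any Hdc-GFPlo library (exact two-sided permutation p = 0.0571, Benjamini-Hochberg 0.229).

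Myeloid progenitor genes were also higher as a list (23 of 27, median log2 fold change 0.44, camera adjusted p = 2.11e-04, or 0.584 with an estimated correlation), and none of them passed edgeR when adjusted over the list alone. Csf1r, the receptor for macrophage colony-stimulating factor, was at 1.78 (SE 0.60; 0.99 to 2.19 over the fits without a library), the transcription factor gene Cebpd at 1.02 (SE 0.42) and the lectin receptor gene Clec12a at 1.12 (SE 0.50). The median of the list depended more on Hdc-GFPhi replicate 1 than on Hdc-GFPlo replicate 4. Mpo, the gene for myeloperoxidase, was counted 38996 times in Hdc-GFPhi replicate 1 and 405 times in Hdc-GFPlo replicate 4 (log2 fold change 0.95, SE 1.27), and the elastase gene Elane 10608 and 0 times in the same libraries. Without Hdc-GFPhi replicate 1 the median of the list was 0.07 (camera adjusted p = 0.0345). Without Hdc-GFPlo replicate 4 it was 0.38 (camera adjusted p = 0.0315), and without both libraries it was 0.01 with a camera adjusted p of 0.781. Here too the mean deviations overlapped (exact two-sided permutation p = 0.286).

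Markers of lymphocytes were few and low. All 9 measured members of the mature lymphocyte list were higher in Hdc-GFPhi (median log2 fold change 0.63, camera adjusted p = 0.0214, or 0.470 with an estimated correlation), none passed edgeR, and the list no longer passed with a stricter filter (median 0.28, adjusted p = 0.126) or with DESeq2 (0.99, adjusted p = 0.111). With no filter the median was 1.43 (adjusted p = 0.00251), so its size depended on the filter. Members that the filter removed include Il2rb, Ncr1, Gzma and Klrd1. They were counted 207, 138, 69 and 37 times in Hdc-GFPhi replicate 3 and at most 1 time in any other library. Their part in the unfiltered value was not tested. Its mean deviation was higher in every Hdc-GFPhi library than in any Hdc-GFPlo library (exact two-sided permutation p = 0.0571, Benjamini-Hochberg 0.229). Log2 fold changes were 1.56 (SE 1.19) for the B cell factor Ebf1 and 0.68 (SE 0.45) for Klrb1c. Lymphoid priming genes had 15 of 24 values higher (median 0.10, 0.04 to 0.18 over the fits without a library; camera adjusted p = 0.0643, or 0.584 with an estimated correlation), and this list passed without Hdc-GFPhi replicate 3 (adjusted p = 0.0105) or Hdc-GFPlo replicate 3 (adjusted p = 0.0141), with no filter (adjusted p = 0.0290) or with the GC and length trend removed (adjusted p = 0.00754). In it Blnk, a B cell adaptor gene, was at 6.29 ± 2.01 against 1.99 ± 0.87 CPM and Cd52 at 39.3 ± 3.85 against 23.6 ± 8.09 CPM. Il7r, the interleukin-7 receptor gene, was counted 34, 20 and 59 times in Hdc-GFPhi and 0, 0, 0 and 9 times in Hdc-GFPlo.

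Erythroid genes (14 of 17 higher, median log2 fold change 0.25, camera adjusted p = 0.0689) and mast cell, basophil and eosinophil genes (7 of 10 higher, median 0.15, adjusted p = 0.704) did not pass. The erythroid list passed without Hdc-GFPhi replicate 3, Hdc-GFPlo replicate 3 or Hdc-GFPlo replicate 4 (adjusted p = 6.70e-04, 0.00474 and 0.0230), its camera adjusted p was 0.701 with an estimated correlation, and its median was 0.06 to 0.53 over the fits without a library. Aqp1 (0.45, SE 0.24), Hemgn (-0.38, SE 0.21) and Epb4.2 (0.87, SE 0.51) led it. Prg2 and Epx, which encode eosinophil granule proteins, were counted 11750 and 1897 times in Hdc-GFPhi replicate 1 and at most 171 and 116 times in any other library, and Il3ra was at 0.58 (SE 0.33).

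Immediate early and dissociation stress genes were higher as a list (28 of 31, median log2 fold change 0.65, camera adjusted p = 1.68e-04, or 0.588 with an estimated correlation), and Hdc-GFPhi replicate 1 stood apart in it. The transcription factor gene Fos was counted 82205 times there and 5691 to 22731 times elsewhere, with Fosb at 62.7 CPM against at most 7.98 and Klf4 at 12.4 CPM against at most 1.07. Without that library the median was 0.09 and the camera adjusted p 0.402, and without both it and Hdc-GFPlo replicate 4 the median was 0.20 and the list passed (adjusted p = 2.75e-05). The mean deviations overlapped (exact two-sided permutation p = 0.371). Gadd45g, a stress-induced gene, was higher in all 3 Hdc-GFPhi libraries (14.0 ± 5.43 against 6.09 ± 1.33 CPM) and did not pass edgeR (adjusted p = 0.239).

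Ribosomal protein genes had small positive values (63 of 69, median log2 fold change 0.20, camera adjusted p = 2.34e-07, or 0.584 with an estimated correlation). The median was 0.08 after a trend with GC content and transcript length was removed, and the list passed there at the preset correlation (camera adjusted p = 0.00852). The mean deviations overlapped narrowly (exact two-sided permutation p = 0.0571, Benjamini-Hochberg 0.229). Rps25 was at 0.29 (SE 0.11), and Rpl15 (-0.43, SE 0.13) and Rps6 (-0.62, SE 0.22) went the other way. Many of these genes, like Gapdh (27 to 143 counts) and Cycs, have near-identical processed copies with which reads can be shared, so their levels are uncertain.

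The remaining lists did not pass the camera test. Oxidative phosphorylation genes were split 27 to 27 (median log2 fold change 0.00, adjusted p = 0.534), with Cox6a1 at 0.26 (SE 0.07), Ndufs7 at 0.22 (SE 0.08) and Cycs at -1.20 (SE 0.38), and passed without Hdc-GFPlo replicate 2 (median 0.06, adjusted p = 0.0134) or, in the other direction, with the GC and length trend removed (median -0.06, adjusted p = 0.0209). With all libraries and an estimated correlation its camera adjusted p was 0.928, and that correlation was not tried in those fits. Interferon response genes had 20 of 35 values higher (0.07, adjusted p = 0.433), with Gbp3 at -0.56 (SE 0.16), Ifitm3 at 0.20 (SE 0.07) and Ifi35 at 0.32 (SE 0.13). Inflammatory signalling genes had 16 of 31 higher (0.05, adjusted p = 0.433), with the NF-kappaB inhibitor gene Nfkbia at 0.33 (SE 0.11), Il6ra at 0.64 (SE 0.26) and Tnfaip3 at 0.44 (SE 0.20), though the mean deviation of that list was also higher in every Hdc-GFPhi library (exact two-sided permutation p = 0.0571, Benjamini-Hochberg 0.229). Genes of MHC class II presentation had 8 of 13 lower (-0.08, adjusted p = 0.497), with H2-DMa at 0.29 (SE 0.11), H2-Aa at -0.41 (SE 0.26) and Ciita at -0.83 (SE 0.64). Glycolysis and hypoxia genes had 22 of 29 lower (-0.05, adjusted p = 0.427), with the hypoxia factor gene Hif1a at -0.45 (SE 0.17), Bnip3 at -0.42 (SE 0.17) and Eno2 at 1.90 (SE 1.06). Endothelial and stromal genes had 7 of 13 lower (median -0.18, mean 0.14, adjusted p = 0.958), with Col4a1 at -0.41 (SE 0.14), Eng at 0.20 (SE 0.10) and Cxcl12 counted 904 times in Hdc-GFPhi replicate 2 and 1 to 69 times elsewhere. None of these genes passed edgeR over all genes or over its list alone, with 1 to 4 per list at an unadjusted p under 0.05, and DESeq2 called Cox6a1 among them.

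**Figure D2:**
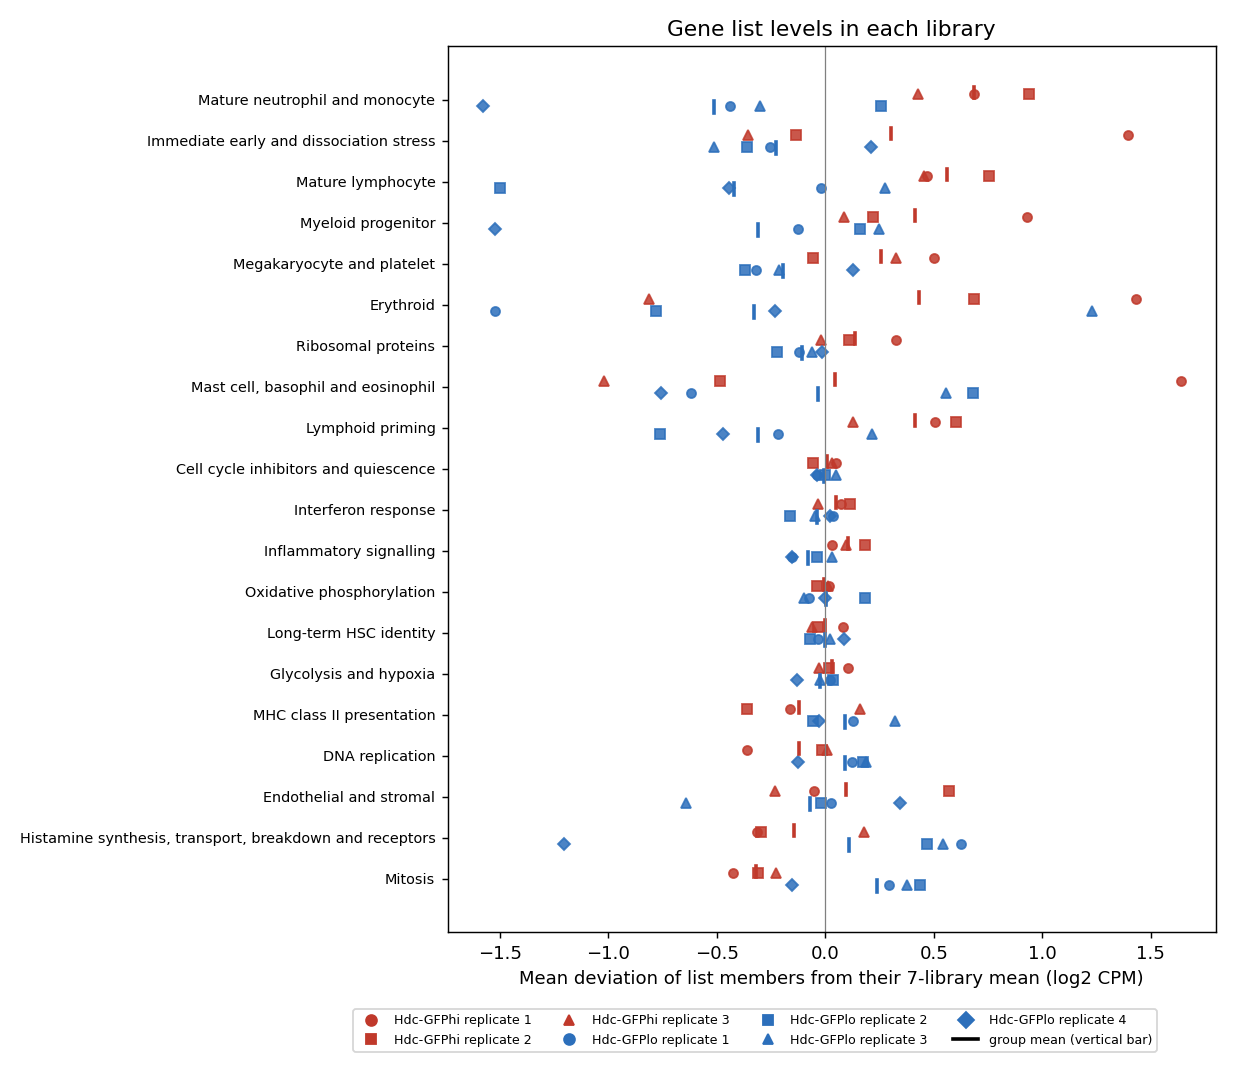
Level of 20 gene lists in each library, as the mean over members of the deviation from the 7-library mean (horizontal axis, log2 CPM). Points are libraries (red Hdc-GFPhi, n = 3; blue Hdc-GFPlo, n = 4) and vertical bars are group means, with lists ordered by their median log2 fold change. Mitosis lay between -0.42 and -0.22 in Hdc-GFPhi and between -0.15 and 0.44 in Hdc-GFPlo, and the immediate early list reached 1.40 in Hdc-GFPhi replicate 1.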

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

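The counts of splits of the libraries were planned, and the other tests of explanations given here were chosen after the result was seen.

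A library of Hdc-GFPlo lay far from the other 3 of its group in 5 of 102 results tested, where 5.1 are expected by chance, and the group of 3 was not tested. Slamf1 was at 61.2 CPM in Hdc-GFPlo replicate 2 and at 55.0 to 55.3 CPM in the others. Mfsd2b was at 121.8 CPM in replicate 3 and at 139.7 to 142 CPM in the others. Rbm44 was at 7.03 CPM in replicate 2 and at 8.19 to 8.26 CPM in the others. Il7r was at 0.435 CPM in replicate 4 and at 0 in the others. The mean deviation of the histamine list was -1.20 on the log2 CPM scale in replicate 4 and 0.47 to 0.62 in the others.

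Lower mitosis genes in Hdc-GFPhi (median log2 fold change -0.56) are not accounted for by GC content or length, since the median was -0.557 with that trend removed, and did not rest on any 1 library, since the value nearest 0 over the 7 fits without a library was -0.519. Chance could not be excluded by the splits, as 2 of 35 gave a median as far from 0 (real value 0.558, highest other 0.623). That other split set Hdc-GFPlo replicates 1 to 3 against the Hdc-GFPhi libraries and Hdc-GFPlo replicate 4, the sample labelled GFP negative. A larger share of cycling progenitors in Hdc-GFPlo stays open. Cd48 and Flt3 had a mean log2 fold change of -0.159, and neither differed by 2 standard errors. As with the mitosis genes, both were higher in Hdc-GFPlo replicates 1 to 3 than in Hdc-GFPlo replicate 4 or any Hdc-GFPhi library. Cd48 was at 39.6 to 49.2 CPM in Hdc-GFPlo replicates 1 to 3, 19.0 in replicate 4 and 30.0 to 36.9 in Hdc-GFPhi. Flt3 was at 74.2 to 83.0, 52.8 and 64.2 to 70.0 CPM in the same order. A lower rate of cycling in Hdc-GFPhi HSCs is a biological hypothesis that these values raise, and it stays open and was not tested separately.

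Higher neutrophil and monocyte genes in Hdc-GFPhi (median log2 fold change 0.78) did not come from Hdc-GFPlo replicate 4 alone, since without it the median was 0.540 and the list passed limma's camera test at the preset correlation, though with an estimated correlation it did not pass even with all libraries (adjusted p = 0.470). Chance could not be excluded by the splits, since 3 of 35 gave a median as far from 0 (real value 0.780, highest other 1.03). RNA of neutrophils or their precursors, which an HSC sort should remove, is a candidate source: the library means of 28 measured neutrophil genes outside every list were higher in Hdc-GFPhi by 0.708 on the log2 CPM scale (SE between libraries 0.283; 0.472 with an SE of 0.202 without Hdc-GFPlo replicate 4), but the groups overlapped (exact two-sided permutation p = 0.0857). Expression of these genes by Hdc-GFPhi HSCs themselves would give the same direction in both sets of genes, so the values do not tell these sources apart and both stay open.

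Higher megakaryocyte and platelet genes in Hdc-GFPhi (median log2 fold change 0.27) are not accounted for by GC content or length, since the median was 0.257 with that trend removed. The splits could not exclude chance, as 7 of 35 gave a median as far from 0 (real value 0.266, highest other 0.550). Platelets or megakaryocytes sorted with the cells cannot be told apart from expression by HSCs: Ppbp and Tubb1, abundant in platelets, differed together by 0.239 CPM with an SE of 4.86, and the bound set for them from the Pf4 difference was 9.86 CPM. The sum of that difference and 2 SEs just exceeds the bound, which keeps this open. A difference between the fractions in HSC expression of these genes also stays open.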

How the results depend on the processing

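The fit with the GC and length trend removed, the fit without Hdc-GFPhi replicate 1 and Hdc-GFPlo replicate 4, and DESeq2 without Hdc-GFPlo replicate 4 were chosen after the data were seen. The cause of each change below was not tested, except where fewer libraries are the setting itself.

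The number of genes passing was 0 under every edgeR and limma alternative and in each fit without a library, 355 with DESeq2 and 414 with DESeq2 without Hdc-GFPlo replicate 4. The log2 fold change of Hdc was 0.73 to 1.28 over the fits without a library. Of 78 other named genes 11 changed sign in some alternative, 26 passed with DESeq2 and 0 passed in any other alternative. With an estimated correlation and with fry's test for a common direction 0 of 20 lists passed, against 8 with the preset correlation, and 6 to 10 passed over the fits without a library. Their medians are the same in those tests: -0.558 for mitosis (fry adjusted p = 0.191), -0.172 for DNA replication (0.372), 0.266 for megakaryocyte and platelet (0.372), 0.437 for myeloid progenitor (0.372), 0.780 for neutrophil and monocyte (0.336), 0.630 for mature lymphocyte (0.191), 0.651 for immediate early (0.498) and 0.203 for ribosomal proteins (0.336). The fry test for either direction, which makes no comparison with genes outside a list, passed the HSC identity list (adjusted p = 0.00490).

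The fits without a library gave medians of -0.263 to -0.0875 for DNA replication and 0.0852 to 0.932 for immediate early genes, each failing the test without Hdc-GFPhi replicate 1 and passing without both it and Hdc-GFPlo replicate 4 (limma adjusted p = 9.33e-06 and 2.75e-05). Mature lymphocyte genes failed with the stricter filter (0.276) and with DESeq2 (0.990), and myeloid progenitor genes without Hdc-GFPhi replicate 1 and Hdc-GFPlo replicate 4 (0.00900).

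The values gave no sign that equal replicate numbers pair the samples. Same-numbered samples had correlations of -0.0399, -0.0345 and -0.139 between their deviations, and samples with different numbers -0.0837 to 0.115. A lack of correlation cannot exclude a shared animal, day or batch, on which the labels are silent. The fit with the replicate block also left out Hdc-GFPlo replicate 4, which has no partner, so it was set against the fit without that library. With the block 0 genes and 7 lists passed, against 0 genes and 9 lists without that library, mature lymphocyte genes had a median of 0.639 and did not pass (0.746 and passing without that library), and Epx turned sign (-2.31 against 3.19). The signs of HSC identity (0.00709), mast cells, basophils and eosinophils (-0.341) and endothelial and stromal genes (0.215) had already turned without that library (0.0167, -0.0601 and 0.184), so the block did not turn them.

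Signs turned as follows. With upper-quartile scaling and with library totals Procr was 0.0145 and 0.0211, the HSC identity list 0.0145 and 0.0211, of which Procr is the median member, and oxidative phosphorylation 0.0287 and 0.0381. With the stricter filter oxidative phosphorylation was 0.00106 and inflammatory signalling -0.0164. With limma and quality weights Prg2 was -0.381, Epx -3.62, oxidative phosphorylation 0.0228 and the endothelial and stromal list 0.192. With the GC and length trend removed Slamf1 was 0.0879, Cox6a1 -0.0439, Ndufs7 -0.00782 and inflammatory signalling -0.0188. Without Hdc-GFPhi replicate 1 and Hdc-GFPlo replicate 4 Hrh2 was -0.138, Mpo -0.539, Prg2 -1.53, Epx -9.03, Klf4 -0.179, the erythroid list -0.0956, the mast cell, basophil and eosinophil list -0.439 and the endothelial and stromal list 0.196.

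Over the fits without a library, ranges that crossed 0 were -0.372 to 0.0333 for Slamf1, -0.0487 to 0.0245 for Procr, -0.245 to 0.114 for Ly6a, -0.130 to 1.64 for Mpo, -1.66 to 5.32 for Prg2, -8.79 to 4.02 for Epx and -1.19 to 3.30 for Cxcl12. For lists they were -0.0324 to 0.0245 for HSC identity, -0.187 to 0.517 for mast cells, basophils and eosinophils, -0.00858 to 0.0738 for inflammatory signalling, -0.0365 to 0.0588 for oxidative phosphorylation and -0.162 to 0.184 for endothelial and stromal genes. Genes that kept their sign but moved more than 1.5-fold were Csf1r (0.993 to 2.19), Clec12a (0.526 to 1.56), Mki67 (-0.458 to -0.188), Flt3 (-0.267 to -0.0721), Cd48 (-0.405 to -0.0458), Cdk6 (0.0515 to 0.118), Hrh2 (0.0644 to 0.872), Maob (-8.46 to -4.75), Il7r (3.35 to 8.21), Ebf1 (0.825 to 3.09), Klrb1c (0.437 to 1.05), Aqp1 (0.286 to 0.685), Hemgn (-0.645 to -0.233), Epb4.2 (0.568 to 1.25), Fosb (0.379 to 3.04), Klf4 (0.168 to 3.21), Il6ra (0.417 to 0.791), Tnfaip3 (0.240 to 0.569), H2-DMa (0.174 to 0.353), H2-Aa (-0.682 to -0.189) and Ciita (-1.13 to -0.402). Lists that did so were histamine (-0.318 to -0.0808), megakaryocyte and platelet (0.213 to 0.437), myeloid progenitor (0.0737 to 0.638), lymphoid priming (0.0415 to 0.180), erythroid (0.0584 to 0.530), quiescence (0.0112 to 0.106), interferon (0.00476 to 0.0956), MHC class II (-0.136 to -0.0176) and glycolysis and hypoxia (-0.0603 to -0.00763), besides DNA replication and immediate early genes given above. Depth limits genes near the floor, such as Il7r and Maob, and not the abundant genes named here.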

Other observations

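The comparison of single libraries with the rest was chosen after the values were seen, and the counts of splits were planned.

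Single libraries carried transcripts of other blood lineages. Hdc-GFPhi replicate 1 held eosinophil transcripts, with 11750 counts of Prg2, 1897 of Epx and 1990 of Ear1. The next highest counts were 171 of Prg2 in Hdc-GFPlo replicate 4, 116 of Epx in replicate 3 and 391 of Ear1 in replicate 2. Alox15, of the same gene list, was counted 795 times in Hdc-GFPhi replicate 1, 397 times in Hdc-GFPlo replicate 2 and at most 43 times elsewhere. Hdc-GFPhi replicate 3 held some transcripts of natural killer cells, with 207 counts of Il2rb, 138 of Ncr1, 69 of Gzma and 37 of Klrd1. The other libraries had 0 counts of these genes, apart from 1 count of Ncr1 in Hdc-GFPlo replicate 1. Klrb1c, of the same mature lymphocyte list, was not confined to that library. It had 47 to 236 counts in every library, the most in Hdc-GFPhi replicate 2. The erythroid gene Rhd was at 622 counts in Hdc-GFPhi replicate 1, 265 in Hdc-GFPhi replicate 2 and 456 in Hdc-GFPlo replicate 3, and at most 10 in the other 4 libraries. Slc4a1, the anion exchanger of red cells, was counted 703 times in Hdc-GFPhi replicate 1, 329 times in Hdc-GFPlo replicate 3 and at most 4 times elsewhere.

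Hdc-GFPlo replicate 4 had 0 counts of the granule genes Elane, Ctsg and Mmp8, where the other 6 libraries had at least 974, 234 and 67, and 405 counts of Mpo, where the others had at least 4762. The upper limit that its count of 0 allows is 0.145 CPM. It had 92 counts of Hdc and 1 of Hrh2, the lowest of all libraries for both.

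Among the 35 splits of the 7 libraries into 3 and 4, the real split gave the highest number of DESeq2 calls (1 of 35 as large; 355 against at most 287 in another split). The same held for genes at an unadjusted p under 0.05 with edgeR (1 of 35, with 1579 against at most 1337). This share of 0.0286 is the smallest that 35 splits allow, and it was not adjusted for the number of split tests. Chance is therefore made less likely for both counts but is not excluded. In both cases the next highest split set Hdc-GFPlo replicates 1 to 3 against the rest, which places Hdc-GFPlo replicate 4 with Hdc-GFPhi. Across genes that library was not closer to Hdc-GFPhi. Its log2 CPM correlated at 0.930 to 0.939 with the Hdc-GFPhi libraries and at 0.908 to 0.945 with the others of its group. The number of genes passing edgeR was 0, for which splits cannot tell anything about chance. The number of lists passing was 8 and reached 10 in another split, with 10 of 35 splits giving as many, so chance was not excluded for it.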
